A study of Mus musculus with 12 samples.

How the data were processed

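RNA sequencing was performed on 12 libraries from brains of 5xFAD mice, a transgenic Alzheimer's disease model, and the labels give microglia as the cell type. The mice were injected daily for 1 week with beta-hydroxybutyrate (BHB, a ketone body) or vehicle, and the titles give 3 libraries for each of 4 groups: Vehicle male, Vehicle female, BHB male and BHB female. Libraries were made from poly(A)-selected RNA. Per the labels, the authors used Trimmomatic 0.39, HISAT2 2.2.1, featureCounts 2.0.3 and DESeq2 2.11.40.8 with the genome build mm10; the annotation used for counting is not stated.

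The deposited table holds a normalised signal: gene counts that the authors divided by 1 DESeq2 size factor per library. It has 57126 rows of Ensembl gene identifiers and 12 library columns, all of which were used. In each column 100% of the values were whole multiples of 1 step, within a tolerance of 0.01, so whole reads were recovered by dividing by that step. Library totals ranged from 4562689 to 6539261 assigned reads, which limits the precision of low values; totals cover counting error only. Within each group, no library was a copy of another, the lowest chi-square per degree of freedom between replicates being 7.02. Pairs of libraries from different groups were not compared in this way. Rows were annotated with GENCODE M21 (GRCm38), which holds 51884 of the identifiers; the 5242 identifiers absent from it carried 1.35% of the summed values.

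Row names were checked without use of the groups, after near-0 values had been seen in rows of ubiquitous genes. Along each chromosome, the protein-coding genes (17429 in all) were scored by whether their mean normalised count reached 50, which 25.5% did. Stretches scoring above 10.7, the 95th percentile of the maxima of 100 permutations, were taken (19 stretches), and those of at least 5 Mb with at least 70% of genes at 50 or more were kept (4 stretches), together with the mitochondrial genome. A set of 1263 anchor genes from 19 widely expressed families, such as ribosomal and proteasome subunits, served as a check, though not every member is expressed in every cell. For this check the stretches were also set without these genes. Outside the kept stretches a value is given only as that of "the row named" for a gene.

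Tests used limma 3.58.1 in R 4.3.3, with trended empirical Bayes, two-sided, on log2(normalised count + 1). The model had 1 mean per group. The 10946 rows with a normalised count of at least 10 in at least 3 libraries were tested, of which 572 lay in kept stretches, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 5%. The contrasts were BHB against vehicle in both sexes (the unweighted mean of the effects in females and males), in females and in males, the difference between these effects, and females against males within each treatment. The contrasts, the 33 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Lists with at least 5 tested members (26 lists) were tested with camera at a preset correlation of 0.01, adjusted over the lists within each contrast.

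The rule for named genes took, per contrast, up to 10 genes per direction past the threshold, or the 5 with the smallest p per direction where none passed. It left out predicted genes, pseudogenes with symbols in -ps and identifiers absent from GENCODE M21. It also took 18 fixed microglial and ketone-related genes, list members and sex-linked genes. Because names held only in part of the genome, the rule was applied also to kept stretches alone. None of the fixed genes lay in a kept stretch, so no value is given as that gene's. Errors are standard deviations of 3 libraries (SD) or standard errors of a log2 difference from limma (SE).

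Measures with 1 value per library were compared by exact two-sided permutation tests, with treatment labels permuted within labelled sex (400 assignments). These were the share of normalised counts in the 37 rows of the mitochondrial genome, and the mean log2 value of gene sets in kept stretches: 14 neuronal, 4 striatal, 6 myeloid and 2 other glial genes, and 4 subunits of oxidative phosphorylation. The cell type sets were chosen after values had been seen. The 6 measures were adjusted together.

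Alternatives were pseudocounts of 0.5 and 10, no filter or a minimum of 50, quantile normalisation, TMM rescaling, a replicate block, arrayWeights, no sex term, leaving out each of the 12 libraries in turn, and edgeR 4.0.16 and DESeq2 1.42.0 on whole reads; lists were also tested with an estimated correlation and with fry. Alternatives added after seeing the data left out rows, libraries or groups in doubt. On simulated counts with the observed depths and dispersions, limma recovered 87.9% of 4-fold, 37.3% of 2-fold and 16.4% of 1.5-fold changes in the contrast over both sexes. In females it recovered 69.7%, 22.4% and 1.49%, and in males 75.8%, 25.4% and 5.97%. False calls over both sexes, in females and in males were 1, 7 and 4 with limma, 1, 8 and 2 with edgeR, and 20, 14 and 19 with DESeq2. By this simulation, calls by DESeq2 alone are the least secure. It drew each row independently, in 1 simulated data set, without structure shared by the rows of a library. Its counts of false calls and recovered changes may therefore not carry over to the real libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.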

Results

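Transcripts were counted in 12 brain libraries labelled microglia, from 5xFAD mice given BHB or vehicle for 1 week, with 3 libraries in each combination of treatment and sex. Assigned reads ranged from 4748728 to 5266558 in Vehicle male, 4562689 to 6539261 in Vehicle female, 5599098 to 6260125 in BHB male and 4654084 to 5523599 in BHB female libraries. Levels are given as normalised counts.

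Most rows of genes from widely expressed families were low: of the 1263 anchor genes, 359 reached a mean of 50 (28.4%). The row named Eef1a1, a translation elongation factor, had a mean of 0.0869 over the 12 libraries, and that named Actb a mean of 11.9. The rows named Hexb, C1qa and Trem2, genes abundant in microglia, held 0 in every library. In 4 stretches of the GRCm38 genome, most ubiquitous genes reached 50: chromosome 4 from 3549041 to 59904737, chromosome 6 from 4003904 to 30509783, chromosome 15 from 8967949 to 38692446 and chromosome 18 from 3266048 to 10818704. These stretches were chosen by the share of protein-coding genes at 50 or more. When they were set again without the anchor genes, 52 of 57 anchor genes inside reached 50 (91.2%), against 330 of 440 other protein-coding genes inside (75%, two-sided Fisher exact p = 0.00442). Outside, 307 of 1206 anchor genes (25.5%) and 3763 of 15726 other genes (23.9%) did (two-sided Fisher exact p = 0.235). All 13 protein-coding rows of the mitochondrial genome reached 50. Gene-level statements are limited to these stretches and the mitochondrial genome.

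**Figure D1:**
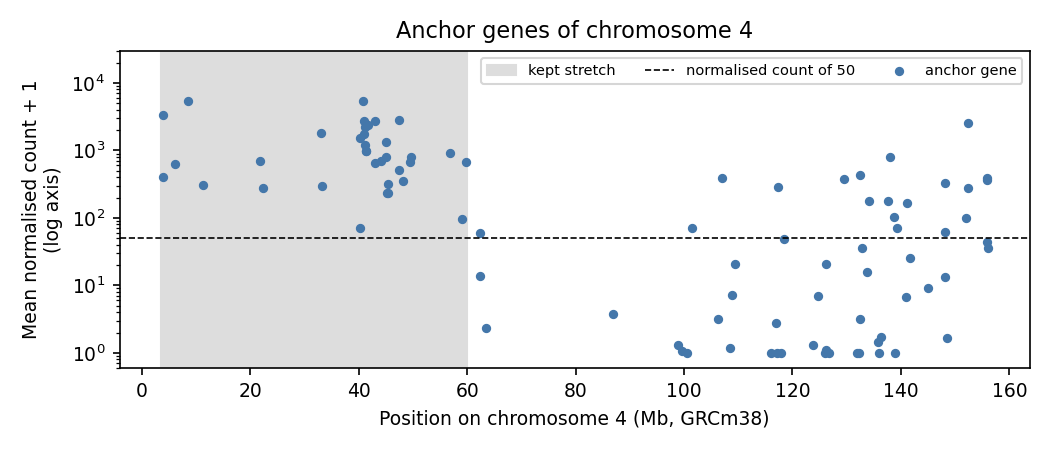
Mean normalised count plus 1 over 12 libraries (log axis) of each anchor gene against its position on chromosome 4 (Mb, GRCm38), with the kept stretch shaded and a dashed line at a normalised count of 50. An unbroken run of 36 anchor genes from Rps20 to Prpf4 lies above the line, where shuffled anchors gave a run of at most 13.

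Genes of neurons were abundant in every library. In the kept stretches, the growth-cone protein gene Basp1 had a mean of 12230 (range 8916 to 19304), the calcium sensor gene Ncald 7608 (3618 to 9879), the enkephalin precursor gene Penk 5564 (726 to 13804) and the GABA-B receptor gene Gabbr2 4616 (3291 to 6272). Glial genes followed, with Ptprz1 of astrocytes and oligodendrocyte precursors at 2875 and Gpr37 of oligodendrocytes at 1937. Genes of myeloid cells were mostly lower: the TGF-beta receptor gene Tgfbr1 was at 582, the interferon regulatory factor gene Irf5 at 258, the kinase gene Lyn at 225 and Cd72 at 55.9. The neuronal glutamate receptor gene Grm8, at 182, was below the first 3 of these. The median neuronal gene exceeded the median myeloid gene in each of the 12 libraries, the lowest ratio being 11.36. The mean log2 value did not differ detectably between BHB and vehicle within labelled sex for neuronal genes (-0.02, exact permutation p = 0.91), myeloid genes (0.10, exact permutation p = 0.49) or other glial genes (-0.08, exact permutation p = 0.78), with adjusted p of 0.91, 0.735 and 0.91 over 6 measures. These means hold differences of 0.22 in females and -0.26 in males for neuronal genes (exact permutation p = 0.3 and 0.4), 0.28 and -0.08 for myeloid genes (0.3 and 0.8) and -0.14 and -0.03 for other glial genes (0.6 and 1).

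**Figure D2:**
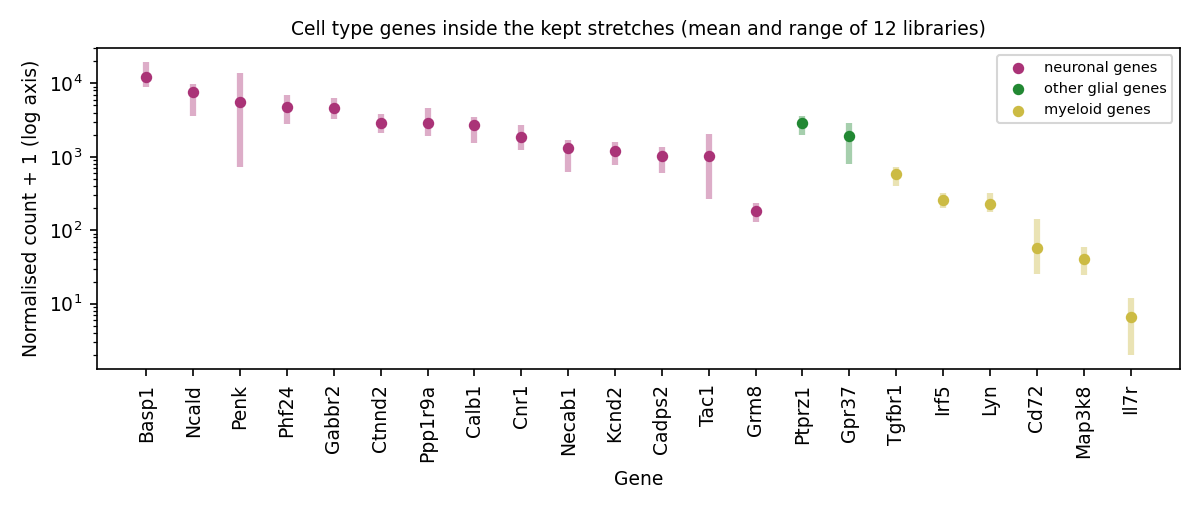
Normalised count plus 1 (log axis) of neuronal, other glial and myeloid genes in the kept stretches, with points for the mean and bars for the range of 12 libraries. Basp1 has the highest mean at 12230 and the myeloid gene with the highest mean, Tgfbr1, stands at 582.

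The main question of the series is what BHB changes in these cells. Mitochondrially encoded transcripts, the core subunits of the respiratory chain and ATP synthase, were higher with BHB: of the list's 13 members, 13 were higher over both sexes, with a median log2 difference of 0.33 (camera adjusted p = 0.000183). The call was lost with an estimated correlation (adjusted p = 0.802), with fry (adjusted p = 0.147) and with quantile normalisation (adjusted p = 0.799), under which 10 of 13 members were higher with a median of 0.06. Among them, mt-Co1, a cytochrome c oxidase subunit, differed by 0.23 ± 0.19 (SE), mt-Nd2, a complex I subunit, by 0.40 ± 0.18, and mt-Atp6, an ATP synthase subunit, by 0.69 ± 0.25. Group means were 285000 to 362200 for mt-Co1 and 3506 to 7474 for mt-Atp6, and the cause of such unlike levels was not tested. Of the members, 0 passed limma's threshold over all rows and 0 when adjusted over the list alone. The mitochondrially encoded share of normalised counts was 24.0% ± 0.759 (SD, n = 3) in BHB male, 21.8% ± 0.992 in BHB female, 21.1% ± 1.36 in Vehicle male and 20.03% ± 0.884 in Vehicle female libraries. The difference within labelled sex was 2.35 percentage points (exact two-sided permutation p = 0.01, 0.06 when adjusted over 6 measures). It was 2.12 without BHB male 1 and BHB male 2 (exact permutation p = 0.05), and 1.96 without these and Vehicle female 2 (0.075). Its male part, as in all comparisons over both sexes, rests on Vehicle male libraries with 8 Y-linked reads in all, and is a comparison between labels; in females alone the difference was 1.78 (exact permutation p = 0.2, where 0.1 is the smallest possible). The 4 nuclear-encoded oxidative phosphorylation genes in kept stretches, Cox6c, Ndufa4, Ndufa5 and Ndufb6, had log2 differences of 0.31, 0.24, 0.32 and 0.31, with a median of 0.31, or 0.20 with quantile normalisation. Their mean differed by 0.30 (exact permutation p = 0.03, 0.09 when adjusted), by 0.25 in females alone (exact permutation p = 0.2), by 0.17 without BHB male 1 and BHB male 2, the libraries highest on the first principal component (exact permutation p = 0.237), by 0.24 without Vehicle female 2, the lowest (0.055), and by 0.12 without all 3 (0.375).

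**Figure D3:**
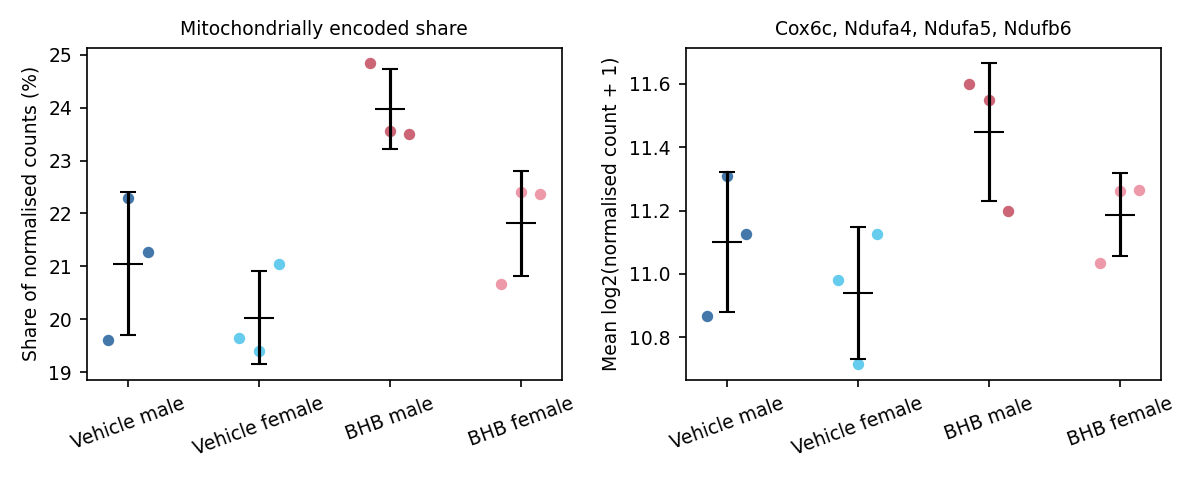
Share of normalised counts in mitochondrial genome rows (%, left) and mean log2(normalised count + 1) of Cox6c, Ndufa4, Ndufa5 and Ndufb6 (right) in 3 libraries per group, with points for libraries and bars for the mean and SD. The group mean share is 24.0% in BHB male and 20.03% in Vehicle female libraries.

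Among individual genes in kept stretches, the neural transcription factor gene Pou3f2 (chromosome 4, 22482780 to 22488366) had the smallest p. It stood at 367 ± 69.2 (SD, n = 3) in BHB male and 356 ± 94.5 in BHB female against 201 ± 29.5 in Vehicle male and 232 ± 20.8 in Vehicle female libraries, a log2 difference of 0.72 ± 0.14 (SE). The other genes with the smallest p and higher values were Tbc1d2 (log2 difference 0.52), the mitochondrial tRNA gene mt-Tm (0.97), Spag1 (0.43) and the interleukin-11 receptor gene Il11ra1 (0.43). Those with lower values were the muscle glycogen-targeting gene Ppp1r3a (-2.77), the tyrosine phosphatase gene Ptpn3 (-0.80), Ugt3a2 (-2.14), the neuronal calcium-binding gene Necab1 (-0.56) and Car8 (-0.45). Levels were low for Ppp1r3a, with group means of 1.68 to 25.1, and for Ugt3a2, with 0.332 to 10.8. Car8 stood at 297 in Vehicle male, 162 in Vehicle female, 162 in BHB male and 160 in BHB female libraries, so its difference rests on Vehicle male. With limma, 0 of the 572 tested genes in kept stretches passed the threshold when adjusted over these alone (smallest adjusted p = 0.0983), while 71 had an unadjusted p below 0.05, 52 higher and 19 lower. DESeq2 called Pou3f2 (adjusted p = 0.00285) and Ptpn3 (adjusted p = 0.0356), and edgeR called 0. In the simulation over both sexes, DESeq2 made 20 false calls, against 1 with limma and 1 with edgeR. That simulation held no structure shared across rows, so these counts may not carry over to the real libraries. Over all 10946 rows, limma called 6 higher and 2 lower, and 1541 had an unadjusted p below 0.05 against 547.3 expected by chance. The higher ones were the Y-linked rows named Ddx3y, Uty, Kdm5d, Eif2s3y and Gm29650 and the row named Ccdc149 (log2 difference 1.08, limma adjusted p = 0.00956); the lower ones were the rows named Gm4846 (-1.14) and Gm26769 (-0.86). edgeR called 0 and DESeq2 26 higher and 35 lower. Without BHB male replicate 3 the limma counts were 66 higher and 378 lower.

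Of the gene lists fixed for microglial states, inflammation, metabolism and cell types, 25 others were tested and none passed (smallest camera adjusted p = 0.227 over both sexes). Most of their rows lie outside kept stretches, so these tests describe rows and not the named genes. Inside the stretches, the homeostatic microglial gene Tgfbr1 differed by 0.02 (log2), the disease-associated microglial gene Ank by 0.13, the interferon-response gene Ddx58 by -0.01, the fatty acid oxidation gene Decr1 by 0.23 and the cholesterol exporter gene Abca1 by -0.42, none past limma's threshold. These values need not be those of microglia, since neuronal genes were abundant in every library and the cells of origin were not determined. Ank had group means of 3572 to 3974, above the mean of 258 of the myeloid gene Irf5. No gene of the ketone body list lay in a stretch.

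In females, the homeobox genes Dlx6 and Dlx5 of GABAergic neurons stood at 379 ± 76.0 (SD, n = 3) and 218 ± 33.9 in BHB female against 150 ± 65.1 and 107 ± 49.8 in Vehicle female libraries, and Penk at 9265 ± 3979 against 3159 ± 2247. The mean log2 value of Penk, Tac1, Dlx5 and Dlx6, chosen after values had been seen, differed by 1.37 (exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). Tbc1d2, encoding a Rab GTPase-activating protein (chromosome 4, 46604390 to 46650209), stood at 249 ± 39.9 against 135 ± 14.5, and Pou3f2 differed by 0.59 (log2). Lower values were seen for Nkain3 (-1.57), Ppp1r3a (-3.58), the activity-induced nuclear receptor gene Nr4a3 (-1.61), Ptpn3 (-1.01) and Gabbr2 (-0.52). Ppp1r3a stood at only 1.68 in BHB female and 25.1 in Vehicle female libraries. Outside kept stretches, the rows taken by the rule for named genes were those named Ccdc149 (1.04), Dnase2a (0.76), Mecp2 (2.99), Polr2j (-0.69), Serpina10 (-1.78) and Ptpn4 (-1.11). The row named Mecp2 was low as well, at 14.5 and 2.04. The mitochondrially encoded list was higher (12 of 13 members, median 0.30, camera adjusted p = 0.0322), with an adjusted p of 0.91 with an estimated correlation and 0.444 without BHB female replicate 3. With quantile normalisation 6 of 13 members were higher (adjusted p = 0.871), and fry gave an adjusted p of 0.614. With limma, 0 rows passed the threshold in either direction (smallest adjusted p = 0.836), 589 had an unadjusted p below 0.05, and edgeR and DESeq2 called 0. In kept stretches alone 0 passed and 27 had an unadjusted p below 0.05.

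In males, the largest differences were in Y-linked rows. The row named Ddx3y, an RNA helicase gene (chromosome Y, 1260771 to 1286629), stood at 905 ± 203 (SD, n = 3) in BHB male and 0.689 ± 1.19 in Vehicle male libraries, that named Eif2s3y at 699 ± 22.4 and 2.07 ± 3.58, that named Kdm5d at 306 ± 66.4 and 0, and that named Uty at 275 ± 49.1 and 0. Over these 4 rows, the libraries labelled Vehicle male held 8 reads in all and the BHB male libraries 6688. These genes are expressed throughout the male body, but the rows lie outside kept stretches, where names are in doubt. The 4 rows summed to at least 1878 in each BHB male library and at most 5.07 in each BHB female library, as Y-linked reads would. On that reading, this contrast compares libraries with and without Y-linked transcripts as well as BHB with vehicle. In kept stretches, the smallest p with higher values were those of Pou3f2 (log2 difference 0.86), Pnrc1 (0.57), mt-Tm (1.39), Rad1 (0.51) and Runx1t1 (0.60). Lower values were seen for Car8 (-0.86), Necab1 (-0.80), the aldolase gene Aldob (-1.49), the forebrain transcription factor gene Fezf1 (-4.72) and Clvs1 (-1.03). Fezf1 stood at 1.31 ± 1.14 in BHB male and 84.4 ± 91.4 in Vehicle male libraries. The mitochondrially encoded list was higher (13 of 13 members, median 0.37, camera adjusted p = 0.000541), with an adjusted p of 0.696 with an estimated correlation, 0.19 with fry, 0.653 with quantile normalisation and 0.0529 without BHB male replicate 1. With limma, 6 rows were higher, all on chromosome Y, and 0 lower; 1092 had an unadjusted p below 0.05, edgeR called 5 higher and 0 lower, and DESeq2 24 and 12. In kept stretches 0 passed limma's threshold and 58 had an unadjusted p below 0.05, while DESeq2 called Car8 (adjusted p = 0.011) and Pou3f2 (adjusted p = 0.0399). Without BHB male replicate 3, 32 rows were higher and 216 lower.

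**Figure D4:**
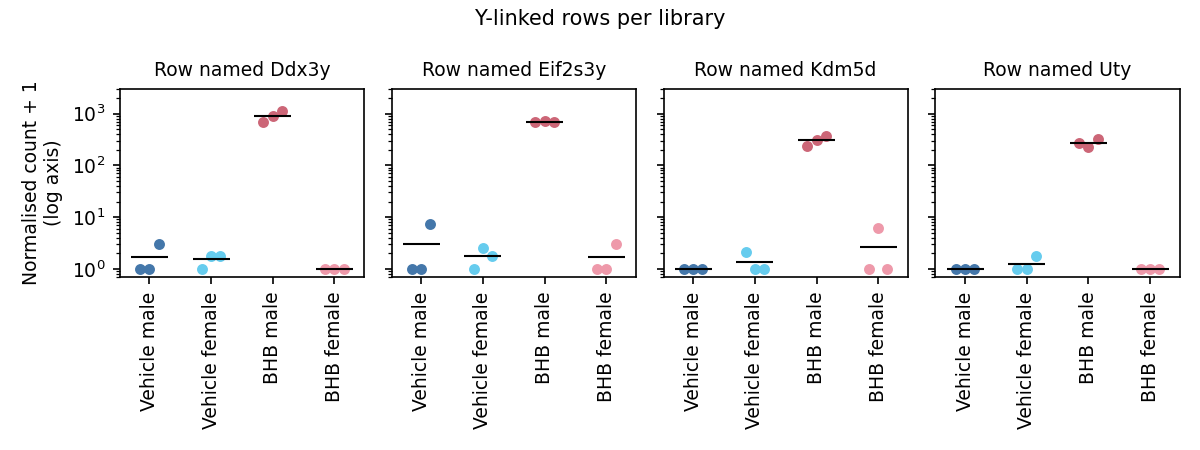
Normalised count plus 1 (log axis) of the rows named Ddx3y, Eif2s3y, Kdm5d and Uty in 3 libraries per group, with points for libraries and lines for the group mean. The BHB male means are 905, 699, 306 and 275, and the highest mean in the other groups is 2.07.

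The BHB effect was compared between libraries labelled female and male with an interaction contrast, on which the 8 Y-linked reads in all of the Vehicle male libraries bear as well. The same Y-linked rows passed, with Ddx3y at -9.81, Eif2s3y at -8.70, Uty at -8.38, Kdm5d at -7.74 and Gm29650 at -7.10 (log2, labelled females minus labelled males). In kept stretches, Nr4a3 had the smallest p: it stood at 219 ± 21.2 (SD, n = 3) in BHB female and 772 ± 537 in Vehicle female, and at 453 ± 41.9 in BHB male and 291 ± 158 in Vehicle male libraries, a difference of effects of -2.42. The others were mt-Nd4l (-1.58), Zfp189 (-1.09), Nkain3 (-1.55) and Smc2 (-0.67), and, with positive differences, Dlx6 (1.63), Car8 (0.83), Penk (3.08), Fezf1 (5.82) and Tbc1d2 (0.69). Group means of mt-Nd4l were only 138 to 355. The adjoining gene mt-Nd4, with means of 101400 to 147500, had a difference of effects of -0.08. Fezf1 varied widely, with 84.4 ± 91.4 in Vehicle male and 1.31 ± 1.14 in BHB male libraries. With limma, 0 rows passed with a positive and 5 with a negative difference, and 344 had an unadjusted p below 0.05; edgeR called 0 and DESeq2 0 and 3. In kept stretches 0 passed limma's threshold and 26 had an unadjusted p below 0.05. The mitochondrially encoded list did not pass (camera adjusted p = 0.825); 1 member passed limma's threshold when adjusted over the list alone, and 0 over all rows.

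The libraries labelled Vehicle female and Vehicle male were compared; since the latter held 8 Y-linked reads in all, this contrast is between labels and cannot be read as one between the sexes. Car8, a carbonic anhydrase-related gene (chromosome 4, 8143362 to 8239041), stood at 162 ± 16.0 (SD, n = 3) in Vehicle female and 297 ± 48.2 in Vehicle male libraries, and mt-Tc, mt-Tn, Cav2 and mt-Atp8 had log2 differences of -0.45, -0.58, -0.68 and -0.88. Higher values in Vehicle female libraries were seen for Nr4a3 (1.37), the pyruvate dehydrogenase kinase gene Pdk4 (0.68), Zfp189 (0.71) and Armc4 (1.89). No Y-linked row passed the threshold. Outside kept stretches, the row named Hba-ps4, a pseudogene that the rule for named genes leaves out, had the smallest limma adjusted p (0.285). The rows taken by that rule were those named Spock2 (0.70), Cbs (1.32), Disp2 (1.62), Ly6k (2.53) and Grk3 (0.70), higher, and Ern1 (-2.69), Zfp759 (-2.99), Dnmt3a (-0.53) and Cct3 (-0.55), lower. With limma, 0 rows passed in either direction and 304 had an unadjusted p below 0.05; edgeR called 0 and DESeq2 2 higher and 1 lower. In kept stretches 0 passed limma's threshold and 16 had an unadjusted p below 0.05. The mitochondrially encoded list did not pass (12 of 13 members lower, camera adjusted p = 0.0746).

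Females and males given BHB differed in Y-linked rows. The rows named Ddx3y, Uty, Eif2s3y and Kdm5d were lower in BHB female libraries, with differences of -9.80, -8.10, -8.92 and -7.37 (log2). The mitochondrially encoded list was lower in females (13 of 13 members, median -0.27, camera adjusted p = 0.000773), with an adjusted p of 0.939 with an estimated correlation, 0.407 with fry, 0.561 with quantile normalisation and 0.341 without BHB male replicate 1. When adjusted over the list alone 1 member passed limma's threshold, against 0 over all rows. In kept stretches, mt-Nd4l (-1.27), mt-Tc (-0.50), the dynein gene Dync1i1 (-0.40), Nkain3 (-1.11) and Smc2os (-1.54) had lower values in females, and Tbc1d2 (0.84), the hypoxia-induced carbonic anhydrase gene Car9 (2.08), Dlx6 (1.12), Fezf1 (4.23) and Pdzd2 (0.68) higher values. Means of mt-Nd4l were 138 in BHB female and 355 in BHB male libraries. The adjoining gene mt-Nd4, at 124100 and 147500, differed by -0.25 ± 0.25 (SE). With limma, 0 rows were higher and 6 lower, and 704 had an unadjusted p below 0.05; edgeR called 0 and 5, and DESeq2 6 and 7. In kept stretches 0 passed limma's threshold and 43 had an unadjusted p below 0.05, while DESeq2 called Tbc1d2 (adjusted p = 0.0475) and mt-Nd4l (adjusted p = 0.0494). Without BHB male replicate 3, 31 rows were higher.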

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

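The tests of row names, sex labels and cell types were chosen after the results were seen, while the splits of the samples were set before their counts were known.

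A difference between the sexes in the BHB effect was found for 5 Y-linked rows with limma: the log2 differences, females minus males, were -9.81 for Ddx3y, -8.70 for Eif2s3y, -8.38 for Uty, -7.74 for Kdm5d and -7.10 for Gm29650. Libraries labelled Vehicle male held almost no Y-linked reads. An exchange of labels with Vehicle female is argued against, since the summed value of 4 Y-linked rows reached at most 2.38 in a library labelled Vehicle female, against at least 1878 in BHB male libraries. RNA of female animals in the libraries labelled Vehicle male may explain the pattern. Their highest summed value was 8.27, or 0.44% of the lowest BHB male value, which restates the pattern and is no separate test. A rise of Y-linked transcripts by BHB is argued against by the same 0.44%, since these genes are expressed throughout the male body and males given vehicle would hold them. These Y-linked rows and those of the other named sex-linked genes lie outside kept stretches. Their names fall under the same doubt as other rows there. The 4 rows summed to at least 1878 in each BHB male library and at most 5.07 in each BHB female library. These values argue against the 4 rows holding reads of genes expressed in both sexes. Which Y-linked gene each row holds stays in doubt, and the argument from expression throughout the male body needs the named genes.

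Rows of ubiquitous genes stood near 0 outside the kept stretches. A displacement by a constant number of rows is argued against, since other shifts of up to 50 rows put at most 268 anchor genes at 50 or more, against 359 as deposited. Absence of the transcripts from the cells is argued against as the whole account, since in stretches set again without the anchor genes 91.2% of these genes reached 50 inside and 25.5% outside. Not every member of these families is expressed in every cell, so absence may account for part of the outside rows. Counting with an annotation of another genome build than the alignment may explain the pattern: names would then hold where coordinates are shared, and the longest unbroken run of anchor genes was 36, against at most 13 in 10000 shuffles.

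Neuronal genes were mostly above myeloid genes in libraries labelled microglia, Basp1, Ncald and Penk being the most abundant, while Grm8 (mean 182) was below Tgfbr1, Irf5 and Lyn. Whether rows inside the stretches hold reads of other genes is not decided by such sets. There 6 of 8 transmitter receptor and channel genes, taken by name alone, reached 50. Of smell and taste receptor genes, also taken by name, 0 of 13 did (two-sided Fisher exact p = 0.000516), and of picked genes of other organs 3 of 49, Aldob, Pon3 and Ttpa (5.84e-05). The stretches were kept for at least 70% of genes, these 8 among them, at 50 or more. Receptor rows of such families rarely reached 50 outside either, 54 of 1504. The check on names inside is that of the anchor genes, 52 of 57 at 50 or more against 330 of 440 other genes. For RNA of neurons and other brain cells, genes were counted. The 6 of 8 were not told from 4 of 11 genes of immune families, also taken by name (two-sided Fisher exact p = 0.17). This was a test chosen after values of both had been seen. That test counts genes at 50 or more and takes no account of level, so it does not decide the question. Of the 4 immune genes, Ccl27a (mean 1453) and Il11ra1 (782) are not in the myeloid set. In level, the ratio of the median neuronal to the median myeloid gene was at least 11.36 in each library. The lowest library values were 3291 for Gabbr2, 3618 for Ncald and 2011 for the glial gene Ptprz1. The highest were 317 for Irf5, 318 for Lyn and 729.5 for Tgfbr1. For these genes, the levels argue against RNA of microglia alone, while the share of other cells was not measured. The 14 neuronal genes were picked after values had been seen, all are genes of brain cells, brain being the labelled tissue, and the series describes isolated microglia but names no sort or gate that would remove other cells.

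The counts of rows past limma's threshold were set beside those of other splits. For BHB against vehicle in both sexes, 5 of 100 sex-preserving splits gave at least the real 8 rows, and the highest other gave 329, so chance was not excluded for the number of rows. For the difference between the sexes, 17 of 100 gave at least the real 5, and the highest other gave 329, so chance was not excluded for the number of rows. The count does not test the rows themselves, of which all 5 real ones were Y-linked. Splits with many times the real count point to a structure of the samples: the highest other split of each contrast also had the largest difference of the 100 on the first principal component, 50.5 and 100.9, against 38.7 and 8.35 for the real one. This comparison was added after the counts were seen. What sets that component was not identified, but the libraries at its ends also lay at the ends of the TMM factors and mitochondrial shares. The contrasts of 3 against 3 libraries have 10 splits, too few for a share under 0.05. In females the real count was 0 and the highest other 1, with 10 splits as large; in males 6 and 127, with 2 as large; between the sexes 0 and 1 with vehicle, with 10 as large, and 6 and 73 with BHB, with 2 as large.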

How the results depend on the processing

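Alternatives on kept stretches, chromosome Y, the Vehicle male libraries, the libraries at the ends of the first principal component, and the mitochondrial share were chosen after seeing the data; the cause of a change was not tested unless fewer rows or libraries account for it. The mitochondrial share's difference kept its direction in every alternative run for it. Differences in mean log2 that had not passed a test turned direction: without both BHB male libraries highest on the first principal component, striatal genes went from 0.49 to -0.01 and other glial genes went from -0.08 to 0.18, and against Vehicle female alone neuronal genes went from -0.02 to 0.06. Alternatives without Vehicle male or against Vehicle female alone leave BHB male libraries with no male vehicle group, so they mix sex with treatment and do not settle the doubt over the sex labels. For BHB against vehicle in both sexes (6 rows higher, 2 lower), counts were 0 and 0 with a minimum of 50, 122 and 403 with arrayWeights, 0 and 0 with edgeR, 26 and 35 with DESeq2, 1 and 1 with no sex term, and 0 and 0 in kept stretches or without chromosome Y rows. Rows lower were 5 with no filter, 0 with the replicate block, 0 without Vehicle male and 4 without both BHB male libraries. Leaving out 1 library gave 6 to 66 higher and 0 to 378 lower. In females, rows lower were 2 without both BHB male libraries, and 0 in all 12 left-out fits. In males (6 higher, 0 lower), rows higher were 2 with a minimum of 50, 90 with arrayWeights, 24 with DESeq2 and 0 in kept stretches or without chromosome Y rows; rows lower were 1 with no filter, 1 with the replicate block, 219 with arrayWeights, 12 with DESeq2 and 4 without both BHB male libraries. Leaving out 1 library gave 5 to 32 and 0 to 216. For the difference between the sexes (0 and 5), rows lower were 3 with a pseudocount of 0.5, 0 with a minimum of 50, 3 with the replicate block, 0 with edgeR, 3 with DESeq2, and 0 in kept stretches, without chromosome Y rows or without both BHB male libraries; left-out fits gave 0 to 1 and 3 to 6. Between the vehicle sexes, counts were 2 and 1 with no filter and 2 and 1 with DESeq2; left-out fits gave 0 to 1 and 0 to 1. Between the BHB sexes (0 and 6), rows higher were 110 with arrayWeights, 6 with DESeq2 and 2 without both BHB male libraries, and rows lower 2 with a minimum of 50, 30 with arrayWeights and 0 in kept stretches or without chromosome Y rows; left-out fits gave 0 to 31 and 5 to 9.

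The mitochondrially encoded list's adjusted p over both sexes was 0.802 with an estimated correlation, 0.147 with fry and 0.799 with quantile normalisation. In females these were 0.91, 0.614 and 0.871, and 0.0544 with the replicate block; in males 0.696, 0.19 and 0.653; between the BHB sexes 0.939, 0.407 and 0.561. Between the vehicle sexes it was 0.0416 with a minimum of 50. Left-out fits ranged from 4.16e-05 to 0.00244 over both sexes, 0.00668 to 0.444 in females, 8.04e-05 to 0.0529 in males, 0.119 to 1 for the difference, 0.00331 to 0.571 with vehicle and 4.02e-05 to 0.341 with BHB. The mitochondrial share's difference was 1.78 percentage points in females (exact permutation p = 0.2), 2.92 in males (0.1), 2.12 without both BHB male libraries (0.05) and 2.86 against Vehicle female alone (0.0357), with 1.99 to 2.66 when 1 library was left out. Without both BHB male libraries and Vehicle female 2 it was 1.96 (exact permutation p = 0.075). The replicate numbers did not pair the libraries: correlations between libraries of 1 number ranged from -0.29 to 0.25.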

Other observations

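The test of oxidative phosphorylation genes was chosen after values had been seen, and the sets of cell type genes as well.

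Genes of striatal and other GABAergic neurons differed in level between libraries. Penk ranged from 726 to 13804 over the 12 libraries and Tac1, the substance P precursor gene, from 265 to 2063. The mean log2 value of Penk, Tac1, Dlx5 and Dlx6 was 9.93 ± 0.34 (SD, n = 3) in BHB female, 8.56 ± 0.92 in Vehicle female, 8.81 ± 1.15 in BHB male and 9.20 ± 0.44 in Vehicle male libraries. Over both sexes it differed by 0.49 between BHB and vehicle (exact permutation p = 0.365, 0.73 when adjusted over 6 measures).

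The first principal component held 32.2% of the variance and set BHB male 1 at 75.0 and BHB male 2 at 48.4 apart from Vehicle female 2 at -52.2.

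One hypothesis is that BHB raised transcripts of oxidative phosphorylation. The nuclear-encoded genes Cox6c, Ndufa4, Ndufa5 and Ndufb6 were higher by a mean of 0.30 on the log2 scale (exact two-sided permutation p = 0.03), in the direction of the mitochondrially encoded genes. Their median difference was 0.31, or 0.20 with quantile normalisation. Other genes in kept stretches differed by like amounts, such as the ribosomal gene Rps20 (0.24) and Decr1 (0.23), while Rpl30 was at -0.26. Of the 71 rows there with an unadjusted limma p below 0.05, 52 were higher and 19 lower. Whether the rise was particular to oxidative phosphorylation was not tested. The adjusted p over 6 measures was 0.09, and the exact permutation p was 0.237 without BHB male 1 and BHB male 2 and 0.055 without Vehicle female 2, so the test leaves the hypothesis open. The doubt over the sex labels of the vehicle libraries bears on it too: in females alone, the difference was 0.25 (exact permutation p = 0.2, where 0.1 is the smallest possible).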
